A study of Ovis aries with 6 samples.

How the data were processed

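Oocytes from antral follicles of sheep (Ovis aries) were profiled by RNA sequencing, with 3 libraries labelled healthy and 3 labelled atretic. The series' design text names Smart-seq2, a full-length method for very small RNA inputs that carries no molecular identifiers. The labels do not say how many oocytes went into a library, or whether the libraries of a group came from different animals. Per the labels' protocols, paired reads of 150 bases were sequenced on an Illumina NovaSeq 6000 and trimmed with Cutadapt 1.9. The aligner, the quantifier, the genome build and the annotation are not given in the sources used here. The follicular fluid proteomics named in the series title was not analysed here.

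Per the file headers, the deposited values are FPKM (fragments scaled to transcript length and to the sequenced total), with 1 value for each of 19474 Ensembl sheep gene identifiers in every library. No counts or read totals accompany these values. Whole-read steps were looked for in the low values. Of 1497 genes under 0.5 FPKM in both of the libraries labelled healthy replicates 1 and 2, the most common ratio between the libraries, to 3 decimals, held 6 genes. For replicates 1 and 3 it held 10 of 1482 genes. No steps were therefore found in the libraries labelled healthy. In those labelled atretic the 2 decimals written are too coarse for this check. Reads were not recovered, the depth is unknown, and no count model, counting interval or detection floor was used.

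The libraries were grouped by their titles. The column headers of the 3 libraries titled healthy start with the letters AO and those of the 3 titled atretic with HO, initials that read as those of the other group. No value that would settle this independently of the labels was found. Directions are given for the libraries as labelled, and every one of them would turn around if the headers were right. The deposited FPKM values of the 2 groups also differ in form: those labelled atretic have 2 decimals throughout, and those labelled healthy have up to 9 with a median of 6. The sources used here do not say whether both groups went through the same processing.

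The files do not pair the gene identifiers with names, and none of the 19474 identifiers occurs in the reference table used here (a RefSeq gene table of the ARS-UI_Ramb assembly, whose column of Ensembl identifiers is empty). The 32 gene lists and cell type marker lists fixed before the data were examined could therefore not be tested. The rule for named genes was applied without its requirement of a gene symbol and with fewer genes per direction than planned. Its parts that rest on the gene lists or on genes fixed by name could not be applied. As applied, the rule took the 2 identifiers per direction with the largest log2 fold change. They came from genes with an adjusted p under 0.05, no overlap between the groups and a mean of at least 5 FPKM in the higher group.

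Genes with at least 1 FPKM in at least 3 libraries were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend and robust prior), using all 6 libraries and no covariate. Adjusted p-values are from the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes on this scale understate the change of genes near or under 1 FPKM. Per-library measures were compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. The p-values measure only the spread between these libraries, which may be technical. The gene test assumes 1 spread per gene for both groups. At 64 FPKM or more the median coefficient of variation was 2.86% in the libraries labelled healthy and 11.1% in those labelled atretic. Its p-values may therefore be too small for genes whose spread lies mainly in 1 group.

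The gene test was tested on simulated data for this comparison, with 9662 genes, the real means and each group's own spread per gene, and 200 changed genes. Of 50 genes changed by 0.5 on the log2 scale 20% were recovered, of 50 changed by 1 it was 68%, of 50 changed by 2 it was 90%, and of 50 changed by 3 it was 96%. Of 158 calls 21 (13.3%) were false, above the nominal 5 per cent. The simulation drew genes independently and took the spread of 3 libraries as the true spread. It also changed far fewer genes than the 8198 called in the real data. The share of false calls and the recovery therefore do not carry over to the real calls. The alternatives covered quantile normalization, median centring, no filter and a filter at 5 FPKM, a pseudocount of 0.1, limma without trend, array weights (which did not converge), the replicate number as a block, each library left out, and a minimum change. Others were chosen after the data were seen: treating the libraries labelled healthy as 1 sample, with and without atretic replicate 3, keeping only genes above 0 in all 6 libraries, rounding the values labelled healthy to 2 decimals, and choosing genes by their mean level in place of the filter for the sets by level. Computations outside R used Python 3.11.15.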

Results

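Transcript levels were measured in oocytes from antral follicles labelled healthy (3 libraries) and from antral follicles labelled atretic, that is, undergoing the degeneration that removes most follicles from the ovary (3 libraries). The series set out to describe how oocytes change in atretic follicles. Each library holds FPKM values for 19474 genes, named only by Ensembl identifier, so genes are described here by level and direction and not by function. Read depth is unknown. The summed FPKM was 949856 ± 1212 (SD, n = 3) in the libraries labelled healthy and 804482 ± 34414 (SD, n = 3) in those labelled atretic. Column headers carry initials that contradict the labels, and all directions below follow the labels.

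Oocytes labelled atretic listed more transcripts than oocytes labelled healthy. Genes above 0 numbered 14359 ± 67.1 (SD, n = 3) in the libraries labelled atretic and 10759 ± 12.2 (SD, n = 3) in those labelled healthy. At 1 FPKM or more the numbers were 9639 ± 323 and 7534 ± 32.7 (SD, n = 3 each), a difference of 2105 genes. At 5 FPKM or more they were 6269 ± 334 and 4827 ± 12.5 (SD, n = 3 each). Very abundant transcripts went the other way, with 114.7 ± 7.5 genes at 1000 FPKM or more in the libraries labelled atretic and 176.7 ± 2.3 in those labelled healthy (SD, n = 3 each). Every library of one group lay beyond every library of the other on each of these measures, and each gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, with 0.11 after Benjamini-Hochberg adjustment over 11 measures. The number of decimals written in the files follows the groups, so these counts cannot be separated from a difference in processing.

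**Figure D1:**
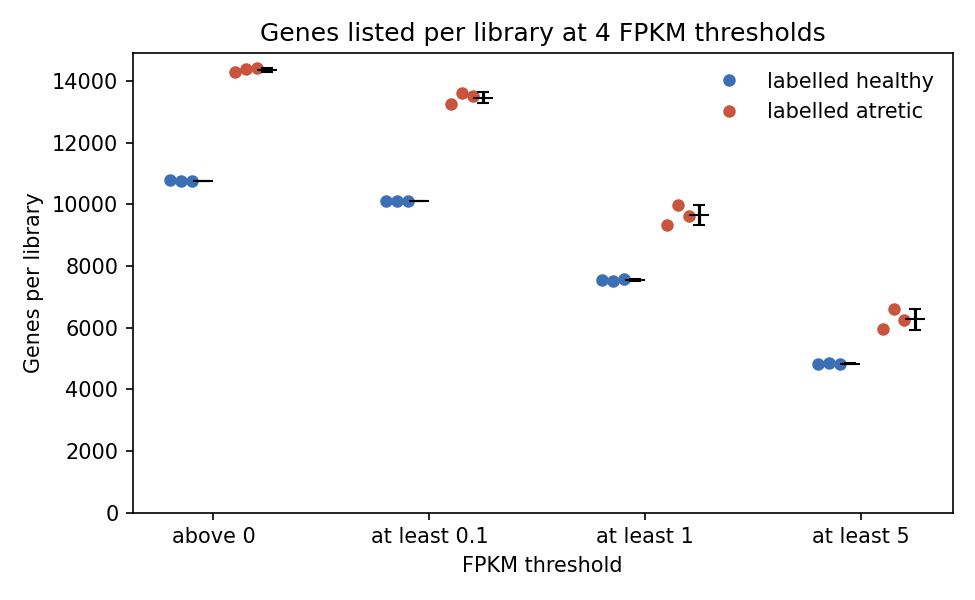
Genes per library (vertical axis) above 0 and at thresholds of 0.1, 1 and 5 FPKM (horizontal axis). Points are the 3 libraries of each labelled group and black bars the mean ± SD. At every threshold the libraries labelled atretic lie above those labelled healthy, with 9639 against 7534 genes on average at 1 FPKM.

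A set of 2356 genes was listed at 0 in all 3 libraries labelled healthy and above 0 in all 3 labelled atretic. Of these genes, 590 were at 1 FPKM or more and 112 at 5 FPKM or more in all 3 libraries labelled atretic. The opposite pattern, listed at 0 in all libraries labelled atretic and above 0 in all those labelled healthy, held for 181 genes, of which 58 reached 1 FPKM and 14 reached 5 FPKM in all 3. Another 9309 genes were above 0 in all 6 libraries and 3021 were listed at 0 in all 6. A listed 0 may be a failed estimate as well as an absent transcript, so no fold is given for any single gene at 0 throughout a group. Those that were tested do enter the distribution and the medians of the fold changes below. Over the 8342 tested genes above 0 in all 6 libraries the median log2 fold change was 0.50, against 0.71 over all tested genes.

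The most abundant transcripts differed between the groups. Of the 100 most abundant genes of each group by mean FPKM, 54 were shared. The overlap between libraries of the same group was not counted, so this number has no baseline. The 100 most abundant genes of each library made up 49.5% ± 0.06 (SD, n = 3) of the summed FPKM in oocytes labelled healthy and 41.5% ± 4.2 (SD, n = 3) in oocytes labelled atretic, with an exact permutation p of 0.1. The share of the 10 most abundant genes was 16.04% ± 0.07 and 18.4% ± 2.9 (SD, n = 3 each), a difference within the spread of the libraries labelled atretic (exact permutation p = 0.4). The most abundant transcript in the libraries labelled atretic averaged 46331 ± 13641 FPKM there and 9891 ± 228 FPKM in those labelled healthy, where it ranked 8th (n = 3 each). It rose by 2.19 ± 0.20 (SE) on the log2 scale, with a limma adjusted p of 3.2e-05. The most abundant transcript in the libraries labelled healthy averaged 28234 ± 663 FPKM there and 6244 ± 2160 FPKM in those labelled atretic, where it ranked 10th (n = 3 each). Its log2 fold change was -2.24 ± 0.24 (SE), with a limma adjusted p of 8.1e-05.

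A large part of the tested genes differed between the groups. Of 9662 genes tested with limma, 5534 were higher and 2664 lower in the libraries labelled atretic at an adjusted p under 0.05, and 1464 did not pass. These calls include 590 higher and 58 lower genes that were listed at 0 in all 3 libraries of the other group. Without those genes, changes of at least 2-fold on the FPKM + 1 scale were found for 3665 higher and 1504 lower genes. Changes of at least 4-fold were found for 1777 higher and 467 lower genes, and of at least 16-fold for 186 higher and 53 lower genes. On the values as deposited, the 2 groups did not overlap in 8444 genes (87.4%), where chance gives 10% on average for 3 against 3. Genes vary together, so a single chance split can lie far from that average, and the 2 shares make no test. The overlap was not counted in the other scalings. The share of higher genes among those called depended on the scaling. It was 67.5% on the values as deposited, where the median tested gene was shifted by 0.71 on the log2 scale towards the libraries labelled atretic. It was 49.9% after quantile normalization and 47.4% after centring each library on the median of its tested genes. In all 3 scalings, 3506 of the 5534 higher genes and 2600 of the 2664 lower genes kept both their call and their direction. Quantile normalization and centring lowered the median log2 fold change to 0.02 and -0.12, so the losses fall mainly on higher genes. The 2 numbers therefore do not show that the lower genes are the firmer calls.

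**Figure D2:**
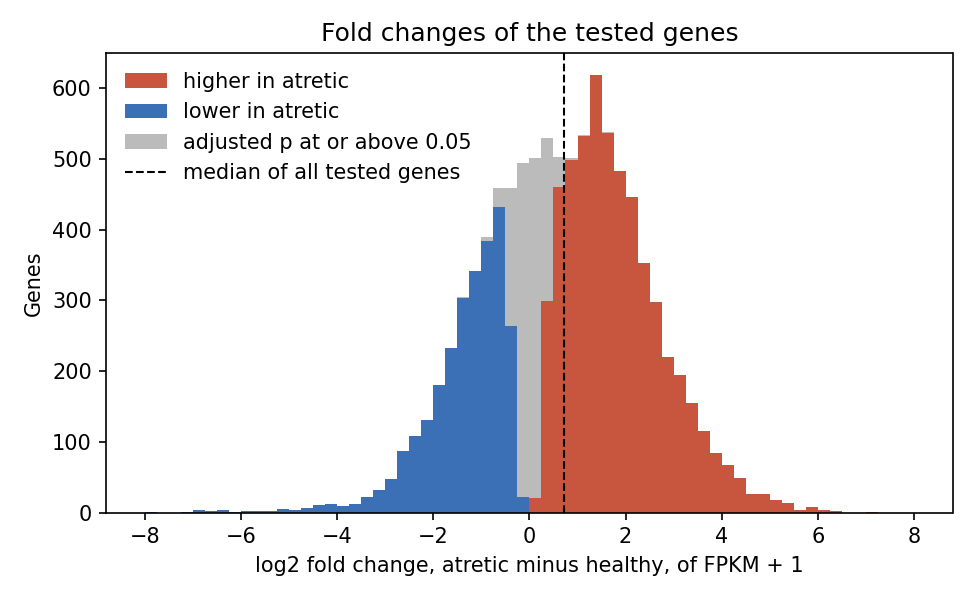
Histogram of the log2 fold change of FPKM + 1 (horizontal axis, libraries labelled atretic minus labelled healthy) for the 9662 tested genes (vertical axis, number of genes). Colours mark the 5534 genes called higher, the 2664 called lower and the 1464 that did not pass, and the dashed line marks the median of 0.71.

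The balance of higher and lower genes differed with the level of the transcript. The tested genes were divided by mean level over all 6 libraries into 4 sets of equal size. In the set with the lowest mean level, 1646 genes were higher and 458 lower in the libraries labelled atretic, with a median log2 fold change of 1.25. In the second set 1469 were higher and 528 lower, and in the third set 1369 were higher and 649 lower. In the set with the highest mean level, above 28.0 FPKM, 1050 genes were higher and 1029 lower, with a median of 0.01. The filter keeps low genes mainly where 1 group is high, which can widen the changes of the lowest set. Over 8889 genes chosen by a mean level of at least 1 FPKM, the median log2 fold change was 1.12 in the lowest of 4 sets. It was -0.04 in the highest, so both were close to those of the tested genes. Over 5369 genes chosen by a mean level of at least 5 FPKM, the median log2 fold change went from 0.74 in the lowest of 4 sets to -0.19 in the highest. Over the 16453 genes above 0 in any library it was 0.09 in the lowest set, under 0.17 FPKM, 0.65 and 0.96 in the next sets and 0.25 in the highest. Over the tested genes, median centring shifts all sets alike and cannot change the order of their medians. Quantile normalization can, and there the medians kept their order over a narrower range, from 0.24 in the lowest set to -0.17 in the highest. In both scalings the majority in the third and the highest set turned to lower genes. After quantile normalization the lowest set had 995 higher and 811 lower genes and the highest set 934 higher and 1120 lower. After median centring the lowest set had 1234 higher and 724 lower genes and the highest set 571 higher and 1479 lower.

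The 2 genes with the largest rise and the 2 with the largest fall were taken from those whose groups did not overlap. ENSOARG00000013902 averaged 4603 ± 294 FPKM (SD, n = 3) in the libraries labelled atretic and 31.8 ± 2.1 FPKM (SD, n = 3) in those labelled healthy. Its log2 fold change was 7.13 ± 0.08 (SE), with a limma adjusted p of 3.4e-08, and 6.31 to 7.22 over the alternatives. ENSOARG00000011610 averaged 357.6 ± 126 FPKM and 3.08 ± 0.21 FPKM (SD, n = 3 each), a log2 fold change of 6.41 ± 0.22 (SE) with a limma adjusted p of 5.9e-07, and 5.58 to 6.76 over the alternatives. In the other direction, ENSOARG00000002463 averaged 433 ± 18.8 FPKM (SD, n = 3) in the libraries labelled healthy. In the libraries labelled atretic it was at 2.86, 0 and 0.6 FPKM in replicates 1, 2 and 3, and its log2 fold change was -7.89 ± 0.44 (SE) with a limma adjusted p of 3.6e-06. It ranged from -9.52 (pseudocount 0.1) to -7.45 over the alternatives. ENSOARG00000024494 averaged 919.99 ± 20.5 FPKM in the libraries labelled healthy and 6.91 ± 5.06 FPKM in those labelled atretic (SD, n = 3 each), a log2 fold change of -7.10 ± 0.47 (SE) with a limma adjusted p of 7.6e-06, and -7.93 to -6.53 over the alternatives. The genomic position and annotation of these genes are not given in the sources used here.

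The spread between libraries differed between the groups. Over the tested genes on the log2 scale, Pearson's r across genes was 0.994 to 0.995 within the libraries labelled healthy, 0.970 to 0.990 within those labelled atretic and 0.716 to 0.804 between the groups. Genes are not independent replicates, so these values describe the libraries only. At 64 FPKM or more the median coefficient of variation was 2.86% between the libraries labelled healthy and 11.1% between those labelled atretic. In the libraries labelled healthy it decreased from 19.7% for genes between 1 and 2 FPKM to 2.09% for genes between 1024 and 2048 FPKM. In the libraries labelled atretic it decreased from 31.6% to 10.4% over the same levels. Among 3462 genes with a mean of at least 20 FPKM in the libraries labelled atretic, replicate 3 lay between replicates 1 and 2 in 77.2%, against 33.5% for the library labelled healthy replicate 3 among 2708 genes. With the libraries labelled healthy averaged into 1 sample and atretic replicate 3 left out, limma called 3393 genes higher and 1272 lower, or 48.3% of those tested, against 84.8% with all libraries. The whole spread of that fit comes from atretic replicates 1 and 2, and the lone averaged sample is assumed to vary like them.

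**Figure D3:**
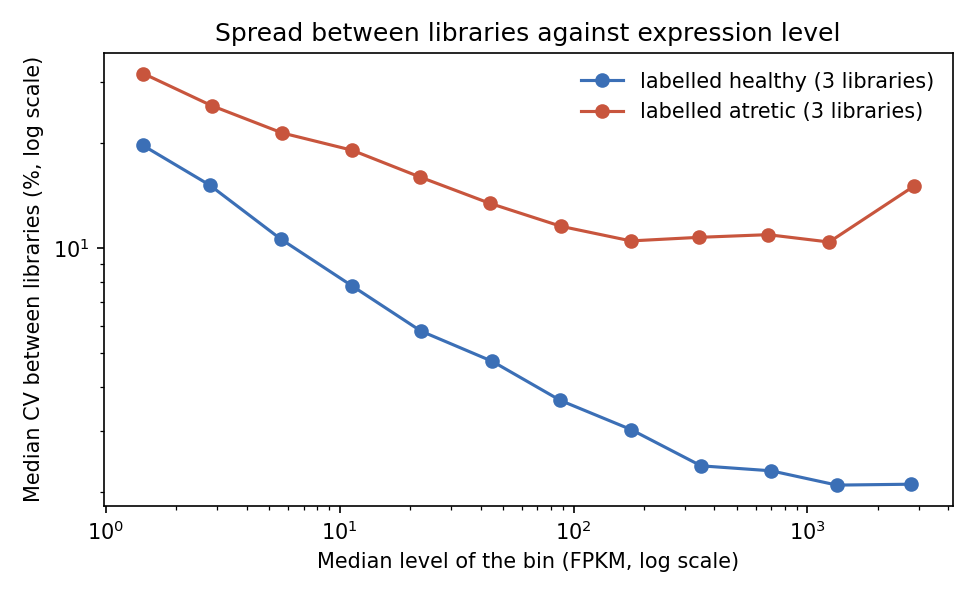
Median coefficient of variation between the 3 libraries of each labelled group (vertical axis, per cent, log scale) against the median level of genes binned by doublings of FPKM (horizontal axis, log scale). The line of the libraries labelled healthy decreases from 19.7% to about 2.1%, and that of the libraries labelled atretic from 31.6% to between 10.4% and 15.1%.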

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

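The tests with the libraries labelled healthy taken as 1 sample, with genes above 0 in all 6 libraries, with rounded values, and of the level sets over other selections of genes were chosen after the data were seen. Quantile normalization gave 3912 higher and 3929 lower genes and median centring 3795 higher genes. Each of these changed the number as reported, but by less than 1.5 times. The number of higher genes (5534) moved by over 1.5 times in 2 of 18 alternatives. It was 3489 with a filter at 5 FPKM, which tests fewer genes, and 3393 with the libraries labelled healthy as 1 sample and no atretic replicate 3, which leaves fewer samples. The number of lower genes (2664) moved in 3 of 18 alternatives. It was 4214 after median centring, which took the median log2 fold change from 0.71 to -0.12, 1562 with a change of at least 2-fold required (58 of them listed at 0 in all libraries labelled atretic), and 1272 with the reduced samples. Without the reduction of the atretic group, taking the libraries labelled healthy as 1 sample gave 4590 higher and 1974 lower genes. In both fits the spread comes from the libraries labelled atretic alone, and the lone sample is assumed to vary like them, so they do not test the spread of the group labelled healthy. Leaving out each library in turn gave 5246 to 5629 higher and 2474 to 2753 lower genes. Of the genes called in both fits, 226 had the opposite direction after quantile normalization and 284 after median centring. Centring moves all genes of a library alike, so the latter number follows from the shift. The 4 named genes kept their direction and call in the 16 or 17 alternatives that tested them, with the ranges of fold given beside each. The difference in genes at 1 FPKM or more kept its direction at the other 2 thresholds and without each library. The planned fit with array weights is not counted among these alternatives: the weights stopped before convergence, with 449 for atretic replicate 3 and under 1 for the others, and gave 6035 higher and 3066 lower genes. With the replicate number as a block, 5433 genes were higher and 2599 lower. No pairing by number was seen: same-numbered libraries correlated at 0.003, -0.03 and -0.02 in their deviations from the group means. Differently numbered libraries correlated at -0.03 to 0.05. The libraries labelled healthy differ so little from each other that this check cannot exclude a pairing. No count-based tool or count normalization could be run, since depth is unknown, and the fixed gene lists could not be matched.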

Other observations

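All tests of explanations below were chosen after the values were seen, except the splits of the libraries and the check of the labels.

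On the values as deposited, the differences within the libraries labelled atretic lay partly along the same direction as the difference between the groups. Across the 9662 tested genes, the change from atretic replicate 1 to atretic replicate 2 correlated with the change from the mean of the libraries labelled healthy to atretic replicate 3 (Pearson's r = 0.50, Spearman's rho = 0.51, with no library used in both). Among 3991 genes at 5 FPKM or more in all 6 libraries, r was 0.36 and rho 0.35. Genes are not independent, and no p is given. Whether atretic replicate 3 is a blend of replicates 1 and 2 stays open below. If it is, the 2 changes do not come from independent libraries. Neither this comparison nor the principal components below were repeated in the other scalings. The median FPKM was 0.81 in atretic replicate 1, 1.11 in atretic replicate 2 and 0.16 on average in the libraries labelled healthy. The median thus rose in both comparisons, and a shift of the whole distribution was not separated from changes of particular genes. Replicate 2 was at least 2-fold above replicate 1 in 1335 genes and at least 2-fold below it in 262. The first principal component held 95.7% of the variance and placed replicates 1, 3 and 2 at 72.8, 87.1 and 108.4, with the libraries labelled healthy between -90.4 and -88.9.

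The real split of the 6 libraries called 8198 genes with limma, and the highest of the other 9 splits called 0 (1 to 9 genes at an unadjusted p under 0.05). It was the only 1 of the 10 splits with a result as large, but 10 splits are too few for a share under 0.05. Every other split mixes the groups, so their difference enters its residual spread.

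The direction of every difference rests on the labels. All 6 libraries have a header initial that reads as the other group's, and with no gene named, no control gene was available to decide which is right. A swap of the 2 groups in the labels or in the headers therefore cannot be told apart from correct labels.

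The 3 libraries labelled healthy differed little from each other. Their coefficient of variation decreased with level with a slope of -0.43 on log axes from 1 to 64 FPKM, where counting noise alone gives -0.5, and the slope between the libraries labelled atretic was -0.24. Above that range it levelled off, at 2.38% from 256 to 512 FPKM and 2.09% from 1024 to 2048 FPKM, so the libraries also differ by a small amount that counting noise alone does not give. The slope up to 64 FPKM is consistent with the hypothesis that they are repeats of 1 preparation or pool, with a small further spread from handling or sequencing that was not tested, in which case the p-values of the gene test overstate the evidence for a difference between follicles. A homogeneous set of separate pools would give the same values, and without read counts the size of the spread, as against its slope, cannot be set against sampling noise.

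The library labelled atretic replicate 3 lay close to a weighted sum of replicates 1 and 2 on the log2 scale, with weights of 0.57 and 0.43. Its residual SD (from the median absolute deviation) over 2169 genes was 0.075, and the residual SDs of the libraries labelled healthy on each other were 0.069 to 0.075. A blend of the other libraries may give this. Libraries placed along 1 gradient would give it as well. This fit does not tell the 2 explanations apart, because both predict intermediate values for the same genes. A weighted sum on the FPKM scale, as a blend would give, was not fitted. Differences between follicles in how far atresia had gone remain open and untested.

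More genes were listed in the libraries labelled atretic. The values argue against 2 technical explanations of the genes above 0 and 1 of the genes at 5 FPKM or more, each taken alone. Rounding the values labelled healthy to 2 decimals set 14.7 genes per library to 0 on average, far fewer than the difference of 3600.3 genes above 0 and in the direction that widens it. A single scaling factor leaves the number of genes above 0 unchanged, so that difference also argues against one as the whole cause. Lower depth of the libraries labelled healthy would leave the number of genes at 5 FPKM or more unchanged, where their coefficient of variation was 10.6% (genes between 4 and 8 FPKM), yet the groups differed by 1442 genes there. Depth as a cause of the zeros of lower genes stays open. A scaling factor was not tested on the genes at 5 FPKM or more. Such a factor there, together with depth at the zeros, therefore stays open as well. Different processing of the groups by the authors cannot be told apart from the group, since the written precision follows it in all 6 libraries, and RNA from other cells and atresia itself remain open and untested.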
